A study of Mus musculus with 9 samples.

How the data were processed

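Poly(A) RNA of activated mouse CD8 T cells was sequenced in 9 libraries, 3 for each of 3 groups, per the labels. RNA came from columns that remove genomic DNA, per the labels' protocols. The tools named, per the submitters' processing notes, were Trim Galore 0.4.5, STAR 2.4, Picard, HTSeq 0.9.1 and DESeq2, and the genome build was mm10, with no role, order or settings given. The annotation used for counting, its treatment of strand and the filter on genes are not given in the sources used here.

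The deposited table held 16344 genes by symbol and 9 columns, 1 per library. Its unit was a signal that the authors made by dividing read counts by a size factor per library, here called normalized counts. This was read from the deposited values themselves, since in each column 100.0% of values were whole multiples of 1 step, within 1e-06 reads, and the steps differed from DESeq2's median-of-ratios size factors by at most 0.00964%. No value was 0, 1 cell was blank (Slc7a5 in NaCl replicate 2) and was left out, and 21 genes had a bare number in place of a symbol, with 20 different numbers, and were not named. The table holds no gene with a 0 in any library, so genes silent in 1 group can be missing from it. Whole reads recovered this way came to 33811363 to 39207045 per library in NaCl, 32738726 to 36088702 in DAHB and 28146402 to 36680103 in DAHB+O.

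Normalized counts were taken to log2 after adding a pseudocount of 1, so a fold change is on the log2(value + 1) scale and understates the change of weak genes. The 14169 genes with a mean of at least 10 over the 9 libraries were tested with limma 3.58.1 (R 4.3.3), with 1 mean per group, a trend in the variance and no block, in 1 fit of 9 libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with calls at an adjusted p under 0.05. Principal components used 14168 genes without a blank. Count tests ran on recovered reads as alternatives. They called 5333 genes higher and 5173 lower (edgeR 4.0.16) and 4974 higher and 5105 lower (DESeq2 1.42.0) in DAHB against NaCl, 4627 and 4417 (edgeR) and 4327 and 4115 (DESeq2) in DAHB+O against DAHB, and 5373 and 5188 (edgeR) and 5058 and 5135 (DESeq2) in DAHB+O against NaCl.

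Gene lists for 37 biological themes, and lists of markers of CD8 T cells and other cell types, were written before the data were examined, as were the groups, tests, alternatives and the rule for naming genes. Lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, two-sided, adjusted over the lists of a comparison. Camera with an estimated correlation, and fry, which tests whether a list moves 1 way on balance, stood beside it. The named genes were, per comparison, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose mean was at least 50 in the higher group, the up to 4 members of each described list with the smallest p, a fixed panel of T cell, metabolic and stress genes, and markers of other cell types. Some genes that this rule names are not reported here. Coordinates came from the GENCODE vM21 annotation of GRCm38 (mm10), matched by symbol, which found 407 of 409 named genes and 79.8% of all genes in the table.

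The test was tested on simulated data made for DAHB against NaCl, with 14182 genes. It recovered 60.0% of genes changed 1.25-fold, 75.5% at 1.5-fold, 86.0% at 2-fold and 100.0% at 4-fold. Each size had 49 or 50 changed genes. Of its 178 calls in this 1 run 10.7% were unchanged genes, above the share the threshold of 0.05 aims at. In the real comparison 73.9% of genes were called, far more than were changed here. Neither the recovery nor the false share therefore carries over to the real calls. In simulated lists among 14168 genes for the same comparison, all 5 changed lists were called by camera with either correlation and by fry. None of the 15 unchanged lists was called by any of them. The simulated genes were drawn independently of each other, so this does not show how the methods do with correlated genes. Overlaps between comparisons that share libraries were set against independent lists and against 20 simulations of unchanged groups. The alternatives were pseudocounts of 0.5 and 10, no filter and a minimum mean of 50, only the 6 libraries compared, the replicate number as a block, TMM rescaling, quantile normalization, a robust variance model, limma-voom, both count tests, a required change of 2-fold, and leaving out each library in turn. A further alternative, the mitochondrial genome list without members under a mean of 1000, was chosen after seeing the data.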

Results

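Messenger RNA was measured in mouse CD8 T cells, the lymphocytes that kill infected or malignant cells, taken from spleen and lymph nodes and activated through CD3 and CD28. About 100000 cells per sample were left overnight in 20 mM NaCl, which served as the control, in 20 mM DAHB, or in DAHB with oligomycin, an inhibitor of mitochondrial ATP synthase, at 10 nM. Each of these 3 groups (NaCl, DAHB and DAHB+O) had 3 libraries, all with 1 batch label. The labels do not spell out the compound behind the abbreviation DAHB, nor repeat its dose for the DAHB+O group, and oligomycin alone was not analysed here. The series concerns how ATP made by mitochondria bears on the differentiation and function of T cells and on chromatin accessibility. Whole reads recovered from the deposited values came to 28146402 to 39207045 per library over 16344 genes. Nothing in the labels says that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

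The groups stood far apart. Principal component 1 held 67.2% of the variance over 14168 genes and separated NaCl from both other groups, and component 2 held 23.4% and separated DAHB from DAHB+O. Across genes, which are not independent replicates, Pearson's r was 0.994 to 0.996 within groups, 0.947 to 0.954 between NaCl and DAHB, 0.946 to 0.948 between NaCl and DAHB+O, and 0.966 to 0.976 between DAHB and DAHB+O. No pair of libraries within a group differed by as little as sampling noise, with a chi-square per gene of 2.25 to 15.2.

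**Figure D1:**
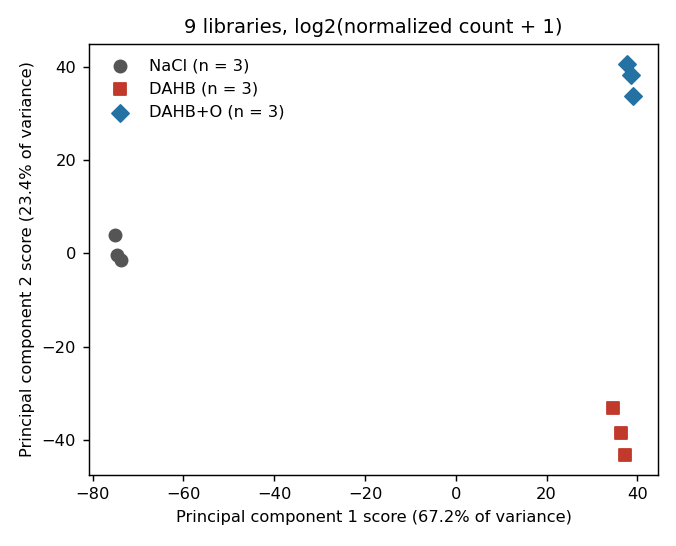
Scores of the 9 libraries on principal components 1 and 2 of log2(normalized count + 1), with the share of variance on each axis and 1 point per library. The 3 groups form separate clusters, NaCl apart from the others along component 1 (67.2% of variance) and DAHB apart from DAHB+O along component 2 (23.4%).

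The comparison of DAHB with NaCl gives the effect of the compound against salt at the same molar dose. Normalized counts are relative to the other genes of a library and do not give RNA per cell. After DAHB they were higher for killing molecules, chemokines and interferon-induced genes and lower for cell division, ATF4 targets and lipid synthesis. Camera called these lists at its preset correlation, and none of the 37 lists with an estimated correlation (lowest adjusted p = 0.267). Prf1, which encodes the pore-forming protein perforin, rose from 9641 ± 1129 normalized counts in NaCl to 79335 ± 4369 in DAHB (SD, n = 3), and Ccl5, a chemokine that attracts T cells, rose from 575 ± 10.3 to 21050.2 ± 222 (SD, n = 3). All 40 tested genes of the G2/M and mitosis list fell, and so did all 40 of the DNA replication list. Of 14169 genes tested with limma, 5031 were higher and 5441 lower in DAHB at an adjusted p under 0.05, and 3697 passed in neither direction. A change of at least 2-fold was reached by 2085 of the higher and 571 of the lower genes. The 3 DAHB libraries did not overlap with the 3 NaCl libraries in 75.6% of genes, where chance gives 10%.

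Cytotoxic effector molecules rose as a group in DAHB, with 11 members higher, 5 lower and 2 not passing (camera adjusted p = 0.0246, and adjusted p = 0.68 with an estimated correlation). Prf1 (chromosome 10, 61297833 to 61304680, coordinates here and elsewhere on mm10) rose by 3.05 ± 0.086 on the log2 scale (SE, adjusted p = 4.46e-13). Gzmb (chromosome 14, 56258838 to 56262260), the serine protease granzyme B that triggers death of target cells, rose 2.02-fold from an already high 245852 ± 2873 to 497521 ± 10663 normalized counts (SD, n = 3). Klrk1, the activating receptor NKG2D, rose 2.06-fold. Of the T cell cytokines and chemokines, 15 rose, 4 fell and 2 did not pass (camera adjusted p = 0.000286, and adjusted p = 0.267 with an estimated correlation). The chemokine genes Ccl3 and Ccl4 rose 33.3-fold and 17.3-fold, and Ccl9 rose from 25 ± 8.15 to 859 ± 32.7 (SD, n = 3). Ifng, the main effector cytokine of these cells, rose from 1468 ± 241 to 5015 ± 870.1 and Tnf from 563 ± 56.4 to 1821 ± 249 (SD, n = 3). Il2, a T cell growth factor, rose from 4.57 ± 0.829 to 123 ± 24.4 (SD, n = 3). Adjusted over the list alone, the counts of both lists were the same.

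Terminal effector differentiation genes rose in DAHB, with 17 members higher, 1 lower and 3 not passing (camera adjusted p = 4.97e-05, and adjusted p = 0.267 with an estimated correlation). Prdm1 (chromosome 10, 44437177 to 44528501), which encodes the transcription factor Blimp-1, rose 8.3-fold from 804 ± 157 to 6607 ± 542 (SD, n = 3). Havcr2, the inhibitory receptor TIM-3, rose 6.29-fold, and Batf, a transcription factor of effector cells, 1.98-fold. The lineage factors Tbx21 and Eomes rose 1.36-fold and 1.81-fold. Type 2 and type 17 T cell genes rose too, 13 of 15, while 2 fell (camera adjusted p = 0.00234, and adjusted p = 0.267 with an estimated correlation). Among them was Il17a, at 28.1 ± 2.31 in NaCl and 221 ± 28 in DAHB (SD, n = 3). Gata3, the transcription factor of type 2 cells, fell 2.0-fold. The counts of both lists were the same when adjusted over the list alone. Of genes of less differentiated cells, Tcf7 fell by 0.50 and Il7r by 0.46 on the log2 scale, while the naive, memory and stem-like list had 15 of 26 members higher and 9 lower (camera adjusted p = 0.147, with the same counts adjusted over the list alone). The receptors Pdcd1 and Lag3 gave log2 fold changes of -0.20 and 0.31, and the transcription factor Tox -0.45, each past the threshold. The call of Pdcd1 was lost without NaCl replicate 1 (adjusted p = 0.0696), DAHB replicate 2 (0.0804) or DAHB replicate 3 (0.0896) and under quantile normalization (0.472).

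Interferon response genes rose in DAHB, with 29 of 40 higher, 5 lower and 6 not passing (camera adjusted p = 1.07e-05, and adjusted p = 0.363 with an estimated correlation). Zbp1 (chromosome 2, 173206612 to 173218923), a sensor of Z-form nucleic acids, rose 7.66-fold from 560.1 ± 19.7 to 4293 ± 70.7 (SD, n = 3). Isg15, a ubiquitin-like protein induced by interferon, rose 11.4-fold, and the guanylate-binding proteins Gbp4 and Gbp7 rose 2.75-fold and 2.37-fold. Markers of dendritic cells moved with this group. Of 11 tested dendritic cell markers 9 were higher and 1 was lower (camera adjusted p = 0.00312, and adjusted p = 0.366 with an estimated correlation). Fscn1 rose 5.04-fold, Cd74 2.42-fold, and the class II genes H2-Eb1 and H2-Aa 2.39-fold and 2.01-fold, while Xcr1, a marker of 1 dendritic cell subset, fell 2.18-fold from 56 ± 15.9 (SD, n = 3). Bst2 belongs to both lists and rose 1.28-fold. With p-values adjusted over the list alone, the counts of both lists were the same.

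Cell division genes fell together. Of the 40 G2/M and mitosis genes none rose (camera adjusted p = 1.19e-17, and adjusted p = 0.267 with an estimated correlation), and of the 40 genes of DNA replication and S phase none rose (camera adjusted p = 1.15e-13, and adjusted p = 0.424 with an estimated correlation). Cdc20 (chromosome 4, 118432901 to 118437352), an activator of the anaphase-promoting complex, fell 4.08-fold from 4849 ± 82.3 to 1190.5 ± 79.2 (SD, n = 3). Ccna2, encoding cyclin A, fell 2.87-fold, the replicative helicase subunit Mcm5 2.7-fold, and the proliferation marker Mki67 2.44-fold from 27272 ± 3709 (SD, n = 3). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 1.64-fold. MYC targets and ribosome biogenesis genes fell, 33 of 42 with 3 higher (camera adjusted p = 3.76e-05, and adjusted p = 0.68 with an estimated correlation), among them Dkc1 (2.0-fold) and the nucleolar protein Ncl (1.52-fold). Myc itself was higher by 0.36 on the log2 scale. In purine and pyrimidine synthesis 15 genes fell and 4 rose of 25 (camera adjusted p = 0.0375, and adjusted p = 0.68 with an estimated correlation), with Gmps, a guanine nucleotide enzyme, 1.87-fold lower. The nucleotide call was lost without DAHB replicate 3 (adjusted p = 0.0702), at a minimum mean of 50 (0.105) and under quantile normalization (0.351). Adjusted over the list alone, the counts of these 4 lists were the same.

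Targets of ATF4 and the integrated stress response, which include the enzymes and carriers that supply amino acids, fell in DAHB, 31 of 40 with 2 higher (camera adjusted p = 1.72e-06, and adjusted p = 0.424 with an estimated correlation). Trib3, a pseudokinase induced by ATF4, fell 4.64-fold from 746 ± 24.8 to 162 ± 27.1, and Asns (chromosome 6, 7675169 to 7693254), asparagine synthetase, fell 2.42-fold from 3246 ± 202 to 1338 ± 55.1 (SD, n = 3). The cationic amino acid carrier Slc7a3 fell 3.93-fold and Phgdh, the first enzyme of serine synthesis, 2.24-fold. Cholesterol biosynthesis genes fell, 18 of 25 with 5 higher (camera adjusted p = 0.00111, and adjusted p = 0.68 with an estimated correlation). Insig1, a sterol-regulated protein of the endoplasmic reticulum, fell 2.5-fold and Acat2 2.95-fold. In fatty acid synthesis and desaturation 13 of 18 genes fell and 2 rose (camera adjusted p = 0.00175, and adjusted p = 0.403 with an estimated correlation), with the desaturases Fads2 4.39-fold and Scd1 2.04-fold lower. 19 cholesterol genes were lower, and the counts of the other 2 lists were the same when adjusted over the list alone.

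Chromatin enzymes fell in several classes. ATP-dependent chromatin remodelers fell in 41 of 45 cases with 2 higher (camera adjusted p = 6.57e-08, and adjusted p = 0.267 with an estimated correlation), among them Smarca2, an ATPase of the SWI/SNF complex, by 2.17-fold, and Phf10 by 1.97-fold. Chd7 went the other way, rising 1.95-fold from 14701 ± 283 to 28760.2 ± 1600.3 (SD, n = 3). Histone and DNA methylation enzymes fell in 28 of 37 cases with 2 higher (camera adjusted p = 1.2e-05, and adjusted p = 0.267 with an estimated correlation), including the histone methyltransferases Suv39h1 (1.98-fold) and Nsd2 (1.75-fold). Histone acetylation and deacetylation enzymes fell in 23 of 34 cases with 6 higher (camera adjusted p = 0.00552, and adjusted p = 0.267 with an estimated correlation). In that list the acetyltransferase Kat7 fell 1.73-fold, while the deacetylases Hdac1 and Sirt2 rose 1.7-fold and 1.83-fold. Under quantile normalization the acetylation list was no longer called (adjusted p = 0.108). With p-values adjusted over the list alone, 42 remodelers were lower, and the counts of the other 2 lists were the same.

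Mitochondrial transcripts took 1.40% ± 0.0149 of normalized counts in NaCl and 2.11% ± 0.242 in DAHB (SD, n = 3). Of the 10 tested messages of the mitochondrial genome 8 rose and none fell (camera adjusted p = 0.0104, and adjusted p = 0.476 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.108). mt-Nd4, a subunit of complex I, rose 1.86-fold from 16067 ± 287 to 30002 ± 3399.9, and mt-Cytb, of complex III, 1.54-fold from 31895 ± 607 to 49418 ± 5436 (SD, n = 3). Nuclear-encoded subunits of complexes III and IV were higher in 14 of 21 cases and lower in 2 (camera adjusted p = 0.0478, and adjusted p = 0.802 with an estimated correlation), with Cox7a2l 1.55-fold higher and Uqcrc1 1.46-fold lower. The call of complexes III and IV was lost without NaCl replicate 1 (adjusted p = 0.118), NaCl replicate 2 (0.055), DAHB replicate 1 (0.0745) or DAHB replicate 2 (0.0861). Adjusted over the list alone, the counts of both lists were the same. Enzymes that handle ketone bodies and hydroxybutyrate moved apart, 6 up and 6 down of 14 (adjusted over the list alone 6 and 6), and the list was not called (camera adjusted p = 0.978). Bdh1 and Oxct1, which oxidise ketone bodies, fell 1.56-fold and 1.55-fold, and the monocarboxylate carrier Slc16a1 fell 1.35-fold. Ldhb and Ldhd, which act on lactate, rose 2.18-fold and 3.88-fold, while Ldha gave 0.07 on the log2 scale (limma adjusted p = 0.202), passing with edgeR (0.0294) and under quantile normalization (0.0423). In glycolysis 11 of 22 genes rose and 3 fell (camera adjusted p = 0.372, adjusted over the list alone 10 and 3), with Hk2, the inducible hexokinase, 2.41-fold higher and Pfkl 2.06-fold lower.

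The genes with the largest rises in DAHB were low in NaCl. Iglon5 went from 4.29 ± 3.69 to 368 ± 11.9 and the small heat shock protein gene Hspb1 from 2.86 ± 1.45 to 186 ± 2.21 normalized counts (SD, n = 3). Tmprss6, a membrane serine protease, rose 55.5-fold to 5867 ± 172, Tns4 71.8-fold to 1996 ± 219, and Mt3, a metallothionein, 46.5-fold to 1919 ± 269 (SD, n = 3). Plat and Pnmal2 were also among the 8 largest, at 62.2-fold and 42.1-fold. The largest falls were smaller, 9.16-fold for the arginine carrier Slc7a2, 7.92-fold for Clec4e, 6.81-fold for the cystine carrier Slc7a11, and 6.63-fold for Cables1. Rises of at least 2-fold reached 32.5% of the 2522 genes with a mean of 10 to 50 normalized counts and 33.5% of the 2004 genes with a mean of 50 to 200, against 2.44% of the 2456 genes with a mean over 3000. Falls of that size stayed between 2.93% and 4.80% over all bins.

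**Figure D2:**
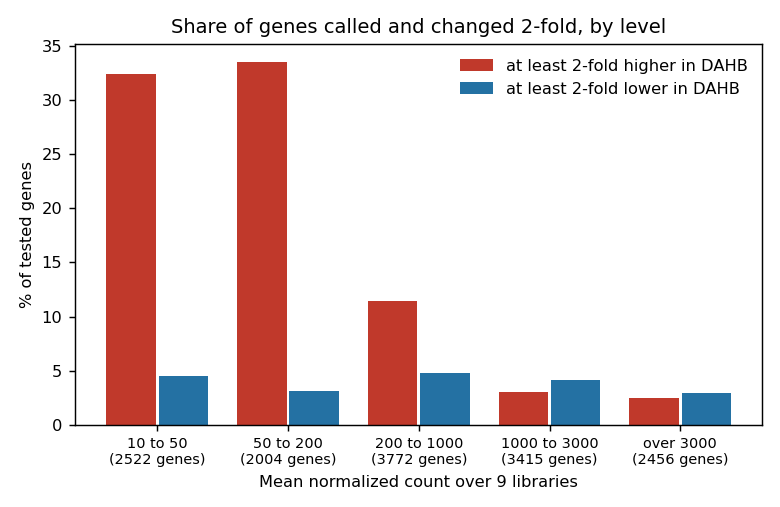
Percent of tested genes (vertical axis) that were called and changed at least 2-fold in DAHB against NaCl, by mean normalized count over 9 libraries (horizontal axis, number of genes in brackets). Bars for rises reach 32.5% and 33.5% in the 2 lowest bins and 2.44% in the highest, and bars for falls lie between 2.93% and 4.80%.

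Markers of other cell types went in both directions. Cd8a stood at 16906 ± 320.3 in NaCl and 22083 ± 762 in DAHB (SD, n = 3), and of the 18 CD8 T cell identity genes 8 rose, 7 fell and 3 did not pass (camera adjusted p = 0.89, with the same counts adjusted over the list alone). Ighm, the immunoglobulin mu chain, fell 3.44-fold from 7254 ± 271 (SD, n = 3). Of 11 tested B cell markers 4 rose and 5 fell, of 9 natural killer markers 4 rose and 2 fell, and of 10 monocyte and macrophage markers 3 rose and 6 fell, with the same counts adjusted over the list alone. Under quantile normalization these counts were 1 and 6, 3 and 4, and 1 and 6. Both tested neutrophil markers rose, Ly6g from 4.22 ± 3.18 to 26.1 ± 16.3 and Cxcr2 from 6.08 ± 3.89 to 29.1 ± 21.2 (SD, n = 3), and the call of Cxcr2 was lost under quantile normalization (adjusted p = 0.095). Of 4 stromal and endothelial markers 3 rose, among them Col1a1 from 37.5 ± 10.1 to 177 ± 12.9 (SD, n = 3), and 1 did not pass. Of 5 markers of CD4 and regulatory T cells 2 rose and 2 fell. These counts were also the same adjusted over the list alone. With an estimated correlation camera gave an unadjusted p under 0.05 in 6 of the 37 gene lists, and fry, which asks only whether a list moves 1 way on balance, called 28. The log2 scale used a pseudocount of 1, so folds understate the change of the weakest genes.

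DAHB+O against DAHB sets cells given the compound and the ATP synthase inhibitor against cells given the compound. It shows the effect of oligomycin only if the dose of DAHB was the same, which the labels do not state. With oligomycin killing molecules, chemokines and glycolysis genes were lower, and ATF4 targets and cell division genes were higher. These lists were called at the preset correlation, and no list was called with an estimated correlation (lowest adjusted p = 0.301). Prf1 fell from 79335 ± 4369 to 8144 ± 1062 normalized counts, and Il10, an anti-inflammatory cytokine, from 3025 ± 353 to 95.6 ± 26.9 (SD, n = 3). Trib3 rose from 162 ± 27.1 to 3573 ± 318 (SD, n = 3). Of 14169 genes 4692 were higher and 4174 lower in DAHB+O, and 5303 passed in neither direction, with 397 and 866 changed at least 2-fold. Groups did not overlap in 67.6% of genes (chance 10%).

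Targets of ATF4 and the integrated stress response rose in 35 of 40 cases and fell in 4 (camera adjusted p = 7.39e-15, and adjusted p = 0.301 with an estimated correlation). Ddit3, which encodes the stress factor CHOP, rose 12.7-fold from 157 ± 9.54 to 2014 ± 76.4 (SD, n = 3). Trib3 (chromosome 2, 152337422 to 152344032) rose by 4.47 ± 0.1 on the log2 scale (SE, adjusted p = 7.73e-14), Asns 6.63-fold and Slc7a3 8.86-fold. Nupr1 and Chac1, further genes of this response, were among the 8 largest rises at 21.6-fold and 12-fold, as was Slc7a11 at 11.3-fold. Others in that set were Thrb, a thyroid hormone receptor, at 9.17-fold, and Snhg5, a host gene of small nucleolar RNAs, at 8.93-fold. Purine and pyrimidine synthesis rose, 17 genes against 5 that fell (camera adjusted p = 0.00505, and adjusted p = 0.432 with an estimated correlation), with the mitochondrial folate enzyme Mthfd2 2.87-fold higher. Genes of the endoplasmic reticulum stress response went the other way, 18 of 27 lower and 5 higher (camera adjusted p = 0.000673, and adjusted p = 0.301 with an estimated correlation), including the chaperones Hsp90b1 (1.77-fold) and Pdia6 (1.96-fold). The counts of these 3 lists were the same when adjusted over the list alone.

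DNA replication genes rose in 39 of 40 cases with none lower (camera adjusted p = 1.36e-13, and adjusted p = 0.312 with an estimated correlation), and G2/M and mitosis genes in 34 of 40 with 1 lower (camera adjusted p = 2.78e-09, and adjusted p = 0.312 with an estimated correlation). Pole, the catalytic subunit of DNA polymerase epsilon, rose 2.23-fold from 2220.2 ± 181 to 4954 ± 177 (SD, n = 3), Cdc45 1.96-fold, the mitotic transcription factor Foxm1 1.89-fold, and Mki67 1.36-fold. MYC targets and ribosome biogenesis genes rose in 36 of 42 cases and fell in 2 (camera adjusted p = 2.08e-10, and adjusted p = 0.38 with an estimated correlation), with Ncl 1.63-fold and the RNA helicase Ddx21 1.69-fold higher, while Myc gave 0.02 on the log2 scale (limma adjusted p = 0.845), passing without DAHB replicate 1 (0.031) and under quantile normalization (0.0487). Cytosolic ribosomal proteins rose in 47 of 65 cases and fell in 1 (camera adjusted p = 5.78e-05, and adjusted p = 0.672 with an estimated correlation). Their changes were small, as for Rpl12 at 0.39 on the log2 scale, and ribosomal protein genes can share reads with processed pseudogenes. Mitochondrial ribosomal proteins rose in 31 of 53 cases and fell in 10 (camera adjusted p = 0.0153, and adjusted p = 0.706 with an estimated correlation), a call lost without DAHB replicate 3 (adjusted p = 0.0619) and under quantile normalization (0.0866), with Mrps10 1.45-fold higher and Mrps21 1.62-fold lower. Chromatin remodelers rose in 25 of 45 cases and fell in 4 (camera adjusted p = 0.00505, and adjusted p = 0.407 with an estimated correlation), Hells 2.44-fold up and Chd7 3.05-fold down. With p-values adjusted over the list alone, 48 cytosolic ribosomal proteins rose and 2 fell and 28 remodelers rose and 5 fell, and the counts of the other 4 lists were the same.

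Cytotoxic effector molecules fell with oligomycin, 16 of 18 with 1 higher (camera adjusted p = 3.2e-07, and adjusted p = 0.301 with an estimated correlation). Prf1 fell 9.78-fold, Gzmb 2.55-fold from 497521 ± 10663 to 195000.0 ± 2225 (SD, n = 3), and Tnfsf10, the death ligand TRAIL, 3.29-fold. Among T cell cytokines and chemokines 12 fell and 7 rose of 21 (camera adjusted p = 0.00978, and adjusted p = 0.301 with an estimated correlation). Il10 (chromosome 1, 131019845 to 131024974) fell 31.9-fold, Ccl5 6.49-fold, Ccl3 4.52-fold and Ifng 1.6-fold, while Tnf rose 1.44-fold and Il2 gave -0.40 on the log2 scale (limma adjusted p = 0.11). Il2 passed with only the 6 libraries compared (adjusted p = 0.0451), with limma-voom (0.0357) and with edgeR (0.0336). Terminal effector differentiation genes fell, 15 of 21 with 1 higher (camera adjusted p = 7.44e-05, and adjusted p = 0.301 with an estimated correlation), including Prdm1 (4.87-fold) and Batf (2.27-fold). Tbx21 and Eomes did not pass, at -0.04 and 0.13 on the log2 scale, although Eomes passed without DAHB replicate 1 (0.325, limma adjusted p = 0.00625). Adjusted over the list alone, the counts of these 3 lists were the same.

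Lists of surface receptor, signalling and T cell subset genes were also called lower at the preset correlation, though not all of their genes fell. Chemokine receptors, integrins and homing genes were lower in 16 of 23 cases and higher in 3 (camera adjusted p = 9.34e-05, and adjusted p = 0.301 with an estimated correlation), with the oxysterol receptor gene Gpr183 5.75-fold lower. Inhibitory receptors and exhaustion-associated genes fell in 14 of 24 cases and rose in 5 (camera adjusted p = 0.012, and adjusted p = 0.301 with an estimated correlation), including Ctla4 (2.97-fold), Lag3 (1.89-fold) and Pdcd1 (1.85-fold), whereas Tox rose 1.66-fold. Early T cell receptor response genes fell in 15 of 31 cases and rose in 6 (camera adjusted p = 0.0188, and adjusted p = 0.38 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.152). Junb, a subunit of the transcription factor AP-1, fell 3.82-fold, and Il2ra, the high-affinity chain of the IL-2 receptor, 2.43-fold from 91739.8 ± 3883 (SD, n = 3). Type 2 and type 17 genes fell in 8 of 15 cases and rose in 2 (camera adjusted p = 0.0397, and adjusted p = 0.301 with an estimated correlation), with Il23r 4.82-fold lower and Gata3 2.14-fold higher. The call of this list was lost without DAHB replicate 3 (adjusted p = 0.0673) or DAHB+O replicate 1 (0.0519), and at a minimum mean of 50 (0.0958). Tcf7 rose 1.47-fold. The counts of these 4 lists were the same when adjusted over the list alone.

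HIF-1 targets, the genes that cells raise in low oxygen, fell in 24 of 25 cases with none higher (camera adjusted p = 5.3e-13, and adjusted p = 0.301 with an estimated correlation). Egln3 (chromosome 12, 54178981 to 54203860), an oxygen-sensing prolyl hydroxylase, fell 6.72-fold from 16549 ± 2589 to 2449 ± 246 (SD, n = 3), the collagen prolyl hydroxylase P4ha2 3.13-fold, the mitophagy receptor Bnip3l 2.78-fold, and the peptide hormone gene Adm, from 84.2 ± 41.1 to 3.13 ± 1.75 (SD, n = 3), 20.0-fold. Glycolysis genes fell in 20 of 22 cases with 1 higher (camera adjusted p = 8.42e-12, and adjusted p = 0.301 with an estimated correlation). The glucose carrier Slc2a3 fell 4.93-fold, the lactate exporter Slc16a3 2.67-fold, Aldoc 6.07-fold, Hk2 2.23-fold and Ldha 1.72-fold. Cholesterol biosynthesis genes fell in 24 of 25 cases with none higher (camera adjusted p = 1.35e-13, and adjusted p = 0.301 with an estimated correlation), among them Lss (2.56-fold) and Hmgcs1 (2.47-fold). Fatty acid synthesis and desaturation genes fell in 14 of 18 cases with 1 higher (camera adjusted p = 4.25e-05, and adjusted p = 0.301 with an estimated correlation), with Scd1 2.49-fold lower. With p-values adjusted over the list alone, 25 cholesterol genes fell, and the counts of the other 3 lists were the same.

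Respiratory chain lists differed in whether they were called. Nuclear-encoded subunits of ATP synthase, the enzyme that oligomycin blocks, fell in 10 of 17 cases with none higher (camera adjusted p = 0.0036, and adjusted p = 0.521 with an estimated correlation), for example Atp5g3 by 1.4-fold, and complexes III and IV fell in 14 of 21 with 2 higher (camera adjusted p = 0.00435, and adjusted p = 0.538 with an estimated correlation), for example Uqcrh by 1.6-fold. Both calls were lost under quantile normalization (adjusted p = 0.0583 and 0.0549). The list of nuclear-encoded complex I subunits was not called, with 15 of 37 lower and 6 higher (camera adjusted p = 0.118). Of the 10 mitochondrial genome messages 4 rose and 5 fell (camera adjusted p = 0.639), with mt-Co1 and mt-Cytb 1.68-fold and 1.64-fold lower and mt-Nd6 and mt-Nd5 1.46-fold and 1.32-fold higher. Under quantile normalization mt-Co1 was higher by 0.16 on the log2 scale (adjusted p = 6.87e-05). The genes mt-Nd5 and mt-Nd6 lie on opposite strands and overlap only at their ends, from position 13552 to 13565. Whether counting used strand is not given in the sources used here, so reads in that short stretch cannot be assigned to 1 of them. Tricarboxylic acid cycle genes rose in 9 and fell in 4 of 24 cases (camera adjusted p = 0.319). Lysosome, autophagy and TFEB targets fell in 19 of 37 cases and rose in 10 (camera adjusted p = 0.0441, and adjusted p = 0.535 with an estimated correlation), with Wipi1 2.34-fold lower, a call lost without DAHB replicate 2 (adjusted p = 0.0523), DAHB replicate 3 (0.0533) or DAHB+O replicate 1 (0.0611). Adjusted over the list alone, 14 complex I genes, 6 mitochondrial genome messages and 20 lysosome genes fell, and the counts of the other 3 lists were the same.

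Other large falls were those of Ccr3, an eosinophil chemokine receptor, from 372 ± 92 to 10.5 ± 1.09, Ace, the angiotensin-converting enzyme, from 221 ± 4.17 to 12.4 ± 3.23, and Mt1, a metallothionein, from 20601 ± 2182 to 1438 ± 148 (SD, n = 3). Cdh17, Grin1 and Timp1 also stood in that set, at 19.6-fold, 16.3-fold and 15.1-fold lower. The genes that mark these cells as CD8 T cells were lower too, 13 of 18 with 2 higher (camera adjusted p = 0.000223, and adjusted p = 0.177 with an estimated correlation, adjusted over the list alone 2 higher and 13 lower). Cd3g fell 1.63-fold, Zap70 1.6-fold and Cd8a 1.34-fold from 22083 ± 762 to 16415 ± 220.2 (SD, n = 3). B cell markers fell in 8 of 11 cases with none higher (camera adjusted p = 0.00404, and adjusted p = 0.177 with an estimated correlation, with the same counts adjusted over the list alone), with Igkc, the kappa light chain, 4.74-fold and Ighm 1.29-fold lower. Both neutrophil markers fell, Ly6g from 26.1 ± 16.3 to 2.46 ± 1.92 and Cxcr2 from 29.1 ± 21.2 to 4.46 ± 3.19 (SD, n = 3). Natural killer markers fell in 4 of 9 cases with 5 not passing, dendritic cell markers fell in 6 of 11 and rose in 3, and neither list was called (camera adjusted p = 0.102 and 0.164). Of monocyte and macrophage markers 3 rose and 3 fell, of stromal and endothelial markers 1 and 1, and of CD4 and regulatory T cell markers 2 and 2. These marker counts were the same adjusted over the list alone. Camera with an estimated correlation gave an unadjusted p under 0.05 in 4 lists, while fry called 29.

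**Figure D3:**
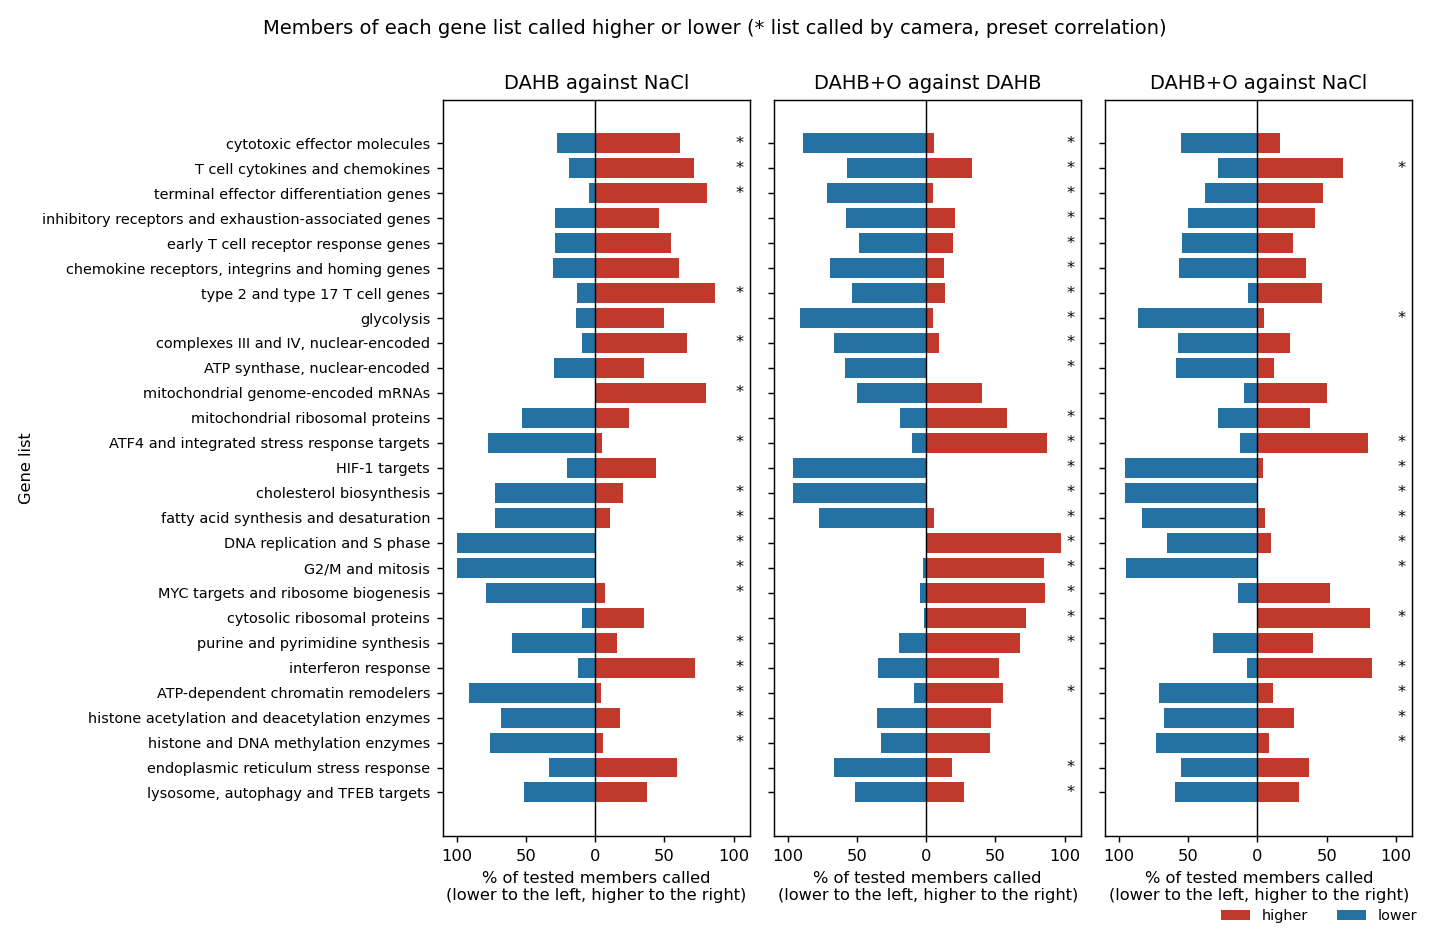
Percent of tested members of each gene list called higher (to the right) or lower (to the left) in each of the 3 comparisons, for lists that camera with a preset correlation called in at least 1 of them, marked by an asterisk in each comparison where called. All 40 G2/M genes were lower in DAHB than NaCl and 34 of 40 were higher in DAHB+O than DAHB, and 24 of 25 HIF-1 targets were lower in DAHB+O than in either other group.

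DAHB+O against NaCl gives the joint effect of both compounds against salt. Interferon response genes and ATF4 targets were higher, and HIF-1 targets, glycolysis, lipid synthesis and mitosis genes lower, than in NaCl. Here too the calls held at the preset correlation and in no list with an estimated correlation (lowest adjusted p = 0.513). Zbp1 stood at 560.1 ± 19.7 in NaCl and 3596 ± 86.6 in DAHB+O, Trib3 at 746 ± 24.8 and 3573 ± 318, and Egln3 at 13235 ± 1168 and 2449 ± 246 (SD, n = 3). Gzmb was 1.26-fold lower than in NaCl, but higher by 0.19 on the log2 scale under quantile normalization (adjusted p = 0.00885). Prf1 gave -0.24 on the log2 scale (limma adjusted p = 0.0187), a call lost without NaCl replicate 2 (0.101), NaCl replicate 3 (0.0693), DAHB+O replicate 1 (0.115) or DAHB+O replicate 2 (0.0591), with DESeq2 (0.0751), with a robust variance model (0.0833) and under quantile normalization (0.643). Of 14169 genes 5178 were higher and 5338 lower, and 3653 passed in neither direction, with 1980 and 858 changed at least 2-fold. Groups did not overlap in 78.7% of genes (chance 10%).

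Interferon response genes were higher in 33 of 40 cases and lower in 3 (camera adjusted p = 1.5e-06, and adjusted p = 0.513 with an estimated correlation), with Isg15 9.54-fold up. Dendritic cell markers moved with them in 7 of 11 cases, with 3 lower (camera adjusted p = 0.13), among them Cd74, 3.96-fold higher, and H2-Ab1, 2.38-fold lower. T cell cytokines and chemokines were higher in 13 of 21 cases and lower in 6 (camera adjusted p = 0.0383, and adjusted p = 0.572 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.0693) and at a minimum mean of 50 (0.0732). Ccl3 was 7.38-fold, Ccl5 5.64-fold, Tnf 4.63-fold and Ifng 2.13-fold higher, and Ltb, lymphotoxin beta, 2.42-fold lower. ATF4 targets were higher in 32 of 40 cases and lower in 5 (camera adjusted p = 6.84e-06, and adjusted p = 0.572 with an estimated correlation), with Ddit3 4.96-fold and Asns 2.73-fold up and Mthfd1l 2.68-fold down. Cytosolic ribosomal proteins were higher in 53 of 65 cases and lower in none (camera adjusted p = 6.06e-06, and adjusted p = 0.83 with an estimated correlation), for example Rps10 by 0.47 on the log2 scale. They took 10.7% ± 0.293 of normalized counts in NaCl, 11.2% ± 0.252 in DAHB and 13.2% ± 0.2 in DAHB+O (SD, n = 3). For cytosolic ribosomal proteins 1 was lower when adjusted over the list alone, and the counts of the other 4 lists were the same.

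Cholesterol biosynthesis genes were lower in 24 of 25 cases and higher in none (camera adjusted p = 1.52e-11, and adjusted p = 0.513 with an estimated correlation), and fatty acid synthesis genes in 15 of 18 with 1 higher (camera adjusted p = 6.84e-06, and adjusted p = 0.513 with an estimated correlation). Insig1 was 5.37-fold, Hmgcs1 4.4-fold, Scd1 5.07-fold and Fads2 8.95-fold lower. HIF-1 targets were lower in 24 of 25 cases and higher in 1 (camera adjusted p = 4.21e-08, and adjusted p = 0.572 with an estimated correlation), and glycolysis genes in 19 of 22 with 1 higher (camera adjusted p = 2.28e-06, and adjusted p = 0.572 with an estimated correlation). Pfkl, the liver-type phosphofructokinase, was 3.45-fold and Tpi1, triosephosphate isomerase, 2.46-fold lower, while Hk2 gave 0.11 on the log2 scale (limma adjusted p = 0.0642). Hk2 passed without NaCl replicate 2 (adjusted p = 0.0439) or DAHB+O replicate 1 (0.0467), with only the 6 libraries compared (0.0107), with TMM rescaling (0.0385), with edgeR (0.0356) and under quantile normalization (2.34e-05). G2/M and mitosis genes were lower in 38 of 40 cases and higher in none (camera adjusted p = 9.03e-13, and adjusted p = 0.513 with an estimated correlation), with Cenpa, the centromeric histone, 3.4-fold and Cdc20 3.16-fold lower. DNA replication genes were lower in 26 of 40 cases and higher in 4 (camera adjusted p = 0.00157, and adjusted p = 0.83 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.183). With p-values adjusted over the list alone, 27 DNA replication genes were lower, and the counts of the other 5 lists were the same.

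Histone and DNA methylation enzymes were lower than in NaCl in 27 of 37 cases and higher in 3 (camera adjusted p = 2.31e-05, and adjusted p = 0.513 with an estimated correlation), with the demethylase Kdm3a 3.27-fold lower. Chromatin remodelers were lower in 32 of 45 and higher in 5 (camera adjusted p = 0.000142, and adjusted p = 0.572 with an estimated correlation), with Baz1a 2.1-fold lower, and histone acetylation enzymes were lower in 23 of 34 and higher in 9 (camera adjusted p = 0.0452, and adjusted p = 0.513 with an estimated correlation), with Hdac7 2.17-fold lower and Hdac1 1.61-fold higher. Under quantile normalization the remodeler and acetylation lists were no longer called (adjusted p = 0.121 and 0.257), and the acetylation list was also lost without NaCl replicate 1 (0.0585) or DAHB+O replicate 3 (0.0557) and at a minimum mean of 50 (0.0677). Adjusted over the list alone, the counts of these 3 lists were the same. Gzma, granzyme A, was 18.8-fold lower, from 5760.0 ± 2080.3 to 311 ± 153 (SD, n = 3), and Tgfb3, a transforming growth factor, 25.1-fold. The largest rises were again in genes low in NaCl, such as Cdc42ep1 (1.63 ± 1.14 to 191 ± 5.55) and the integrin gene Itga9 (1.91 ± 0.844 to 173 ± 13.7; SD, n = 3). CD8 T cell identity genes were lower in 15 of 18 cases and higher in 1 (camera adjusted p = 0.00271, and adjusted p = 0.38 with an estimated correlation), with Zap70 2.0-fold lower, and B cell markers were lower in 7 of 11 (camera adjusted p = 0.0309, and adjusted p = 0.38 with an estimated correlation), with Ighm 4.43-fold and Igkc 7.67-fold lower. The lower counts were 15 and 7 adjusted over the list alone, and 11 B cell markers were lower under quantile normalization. Of natural killer markers 3 were higher and 5 lower, of monocyte and macrophage markers 4 and 4, and all 4 stromal and endothelial markers were higher, with the same counts adjusted over the list alone. With an estimated correlation the unadjusted p was under 0.05 in 2 lists, while fry called 31.

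Taking the comparisons jointly, 7476 genes were called in the same direction against NaCl in DAHB and in DAHB+O, 3687 higher and 3789 lower, and 1067 in opposite directions. Independent lists of these sizes would share 1839 higher and 2049.8 lower genes. Simulated unchanged groups with common NaCl libraries shared 0.05 in each direction on average in 20 simulations. No gene was changed in them, so few were called and a small overlap was fixed in advance. They cannot show how much common libraries add where many genes are called. The fold changes correlated across genes with r = 0.789 (0.498 in the simulations), and their covariance was 0.753 against 0.0118 simulated, a difference of 0.741. With 3 NaCl libraries the controls could not be split, so part of the excess may come from the shared controls. Among these shared calls were Zbp1 and Hspb1, up in both, and Fads2, Insig1 and Cdc20, down in both.

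In DAHB+O against DAHB 4771 of the genes called in DAHB against NaCl changed in the opposite direction. Of these 2060 had risen, such as Prf1, Ccl5 and Prdm1, and 2711 had fallen, such as Asns, Trib3 and Pole. Independent lists would share 1482 and 1802 genes. Simulated unchanged groups with common DAHB libraries shared 0.1 and 0, again small in advance because no gene was changed in them. A further 1089 rose again and 1147 fell again, among the latter Insig1 and Scd1. The fold changes correlated across genes with r = -0.296. The simulations gave -0.499, which comes from the shared libraries alone, so the 2 values of r do not rank the reversal. The covariance of the fold changes was -0.182 against -0.0118 simulated, a difference of -0.17. Part of the excess in counts may come from the shared DAHB libraries, which were too few to split. Of the 2085 genes that rose at least 2-fold in DAHB, 57.6% had a DAHB+O mean between the other 2 groups. At or past the NaCl level were 5.90%, and 36.5% were at or past the DAHB level. The median gene kept 87.2% of its rise, as a share of the log2 fold change and not of normalized counts. That share depended on expression level. It was 86.1% to 91.0% in the bins with a mean of 10 to 1000. At a mean of 1000 to 3000 it was 57.0% (bounds 46.2 to 65.9), and over 3000 it was 40.7% (31.5 to 51.9). These bounds come from resampling genes, which are not independent, and hold no spread between libraries. Of the 571 that fell at least 2-fold, 68.5% lay between and the median gene kept 68.4% of its fall on the log2 scale.

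**Figure D4:**
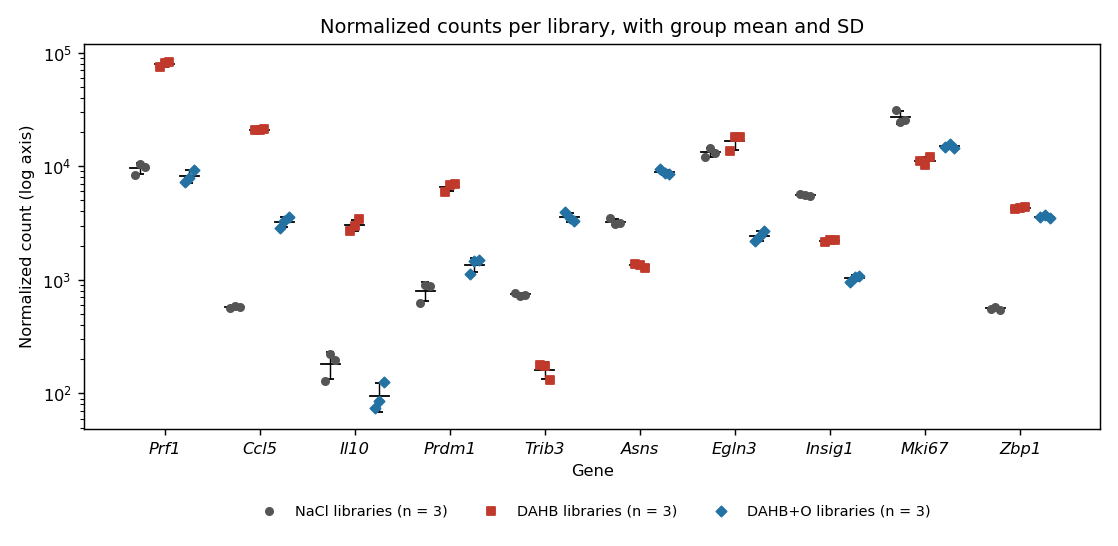
Normalized counts of 10 genes in each of the 9 libraries on a log axis, 1 symbol per library, with the mean (bar) and SD (whiskers) of each group of 3. Prf1, Ccl5, Il10 and Prdm1 were highest in DAHB, Trib3 and Asns were highest in DAHB+O, Egln3 was lowest in DAHB+O, Insig1 and Mki67 were highest in NaCl, and Zbp1 was lowest in NaCl.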

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

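All alternatives here were planned except the mitochondrial genome list without members under a mean of 1000, chosen after seeing the data, which kept its call. With a change of at least 2-fold required, the counts of genes fell by construction. They were 2085 higher and 571 lower in DAHB against NaCl, 397 and 866 in DAHB+O against DAHB, and 1980 and 858 in DAHB+O against NaCl. The genes called in DAHB against NaCl and in the opposite direction in DAHB+O against DAHB fell to 470, and those shared against NaCl to 1733. Under every other alternative the counts of genes stayed within 1.5 times those reported, but similar counts need not be the same genes. Quantile normalization kept 4023 of the 5031 higher and 4575 of the 5441 lower calls in DAHB against NaCl. In DAHB+O against DAHB it kept 4416 of 4692 higher and 3828 of 4174 lower calls. In DAHB+O against NaCl it kept 4298 of 5178 higher and 4463 of 5338 lower calls. Quantile normalization turned the direction of some calls, 10 of the genes higher in DAHB than NaCl, 7 of those lower in DAHB+O than DAHB and 38 of those lower in DAHB+O than NaCl, and the cause was not tested. Among named genes these were Gzmb in DAHB+O against NaCl (0.19 on the log2 scale) and mt-Co1 in DAHB+O against DAHB (0.16). In the latter comparison 3 genes that did not pass changed sign under some alternatives, Tbx21 (0.024 under quantile normalization, -0.119 to 0.0614 without 1 library), Myc (-0.0019 with edgeR, -0.0034 with DESeq2, -0.0608 to 0.129 without 1 library) and Eomes (-0.0167 to 0.325 without 1 library). Myc passed at 0.129 and Eomes at 0.325, both without DAHB replicate 1, and Myc also at 0.176 under quantile normalization. Camera with an estimated correlation called 0 lists higher and 0 lower in each comparison (unadjusted p under 0.05 in 6, 4 and 2 lists), while fry, which compares a list with no other genes, called 13 higher in DAHB than NaCl, and 10 higher and 21 lower in DAHB+O than NaCl. Of the 53 list calls, quantile normalization ended 11 and a minimum mean of 50 ended 4, and the pseudocounts, no filter, TMM rescaling and fry ended none. Libraries with the same number correlated in their deviations at r = 0.0273 to 0.160, over 0.1 in 2 of 9 pairs, so the numbers were not taken to pair them, although all 9 correlated best with their own number. The replicate block gave 5129 higher and 5554 lower genes in DAHB against NaCl, 4826 and 4319 in DAHB+O against DAHB and 5274 and 5444 in DAHB+O against NaCl, and kept 53 of 53 list calls. Among named genes it added the call of Hk2 in DAHB+O against NaCl (adjusted p = 0.010) and changed no other. The 10 splits of the 6 libraries of a comparison are too few for a share under 0.05. The real splits called 10472, 8866 and 10516 genes, 1 split of 10 each, and the highest other called 0 with limma (at most 180, 304 and 101 genes at an unadjusted p under 0.05). The median SE of the log2 fold change was 0.303 for genes with a mean of 10 to 50 and 0.0419 for those over 3000, so smaller changes could be called at higher levels.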

Other observations

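All tests of explanations in this part were chosen after the results were seen. The bound on fewer B cells in DAHB than in NaCl was changed after its first values were known. So was the test of scaling for glycolysis genes. Bounds given in brackets in this part treat genes as independent, which they are not, and hold no spread between libraries. Of 11 tested members of the osmotic stress and NFAT5 list 8 fell and 2 rose in DAHB against NaCl, both given at 20 mM (camera adjusted p = 0.127). Slc5a3, a sodium-coupled inositol carrier, fell 5.05-fold to 574 ± 42.3, Hspa4l, a heat shock protein, fell 2.44-fold, and Sgk1, a kinase that regulates ion carriers, rose from 232 ± 13.1 to 477 ± 23.8 (SD, n = 3). In DAHB+O Slc5a3 was 4.51-fold below NaCl. Of 27 heat shock and mitochondrial protein quality control genes 7 rose and 15 fell in DAHB (camera adjusted p = 0.207), with Hspa1b 3.73-fold up and the mitochondrial protease Lonp1 1.98-fold down. The mitochondrial chaperone Hspa9 fell 1.63-fold in DAHB and rose 2.51-fold with oligomycin, from 13459 ± 971 to 33698 ± 1663 (SD, n = 3). The counts adjusted over the list alone were 2 higher and 8 lower for osmotic stress, and 8 higher and 16 lower for heat shock.

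Genes of cell survival and of less differentiated T cells went both ways in DAHB. Bcl2l11, which encodes the death-promoting protein BIM, rose from 5661 ± 424 to 16928 ± 493 (SD, n = 3), and Bcl2, which protects from death, fell 1.55-fold, among 9 apoptosis regulators that rose and 8 that fell of 25 (camera adjusted p = 0.793). With oligomycin Bcl2l11 fell 2.03-fold and Cflar, an inhibitor of caspase 8, 1.9-fold. Of naive, memory and stem-like genes, Cxcr5 was 3.35-fold and the transcription factor gene Klf2 2.7-fold higher in DAHB. Of the NRF2 and glutathione list 13 rose and 9 fell of 25 (camera adjusted p = 0.372), with Gstp1, a glutathione transferase, 2.68-fold higher and Pgd, of the pentose phosphate pathway, 1.71-fold lower. The counts of the apoptosis and NRF2 lists were the same when adjusted over the list alone.

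Weakly expressed genes rose with DAHB far more often than they fell, 1491 against 176 by at least 2-fold among 4526 genes with a mean of 10 to 200. Scaling by 1 factor per library moves all levels alike. The median log2 fold change of genes at 50 to 200 exceeded that of genes over 1000 by 0.57 (bounds 0.51 to 0.63 over 2000 resamples). This argues against such a factor only. The difference is part of the pattern itself, and scaling that varies with level was not tested on it. Over all levels quantile normalization kept 4023 of the 5031 higher calls. Removal of genes with a 0 in any library was weighed on genes at 200 to 1000 changed 2-fold to 4-fold, too far from 0 to be removed. Of these 287 rose and 173 fell, a ratio of 1.66 (exact bounds 1.37 to 2.02). The lower bound lay above the limit set for removal and below the limit set against it. The excess of rises at that level cannot come from removal, but for the weaker genes removal stayed open. An even background of reads over all exons in DAHB libraries also stayed open. The share of genes below 0.25 of the median gain per kb was 7.39% (exact bounds 6.48 to 8.38), between the limits set for and against it. Besides, only 67.0% of genes at 10 to 200 had an exon length, too few for the test to count. A response to DAHB that oligomycin does not remove may contribute. The weak genes that rose at least 2-fold kept a median of 89.0% of their log2 rise in DAHB+O (bounds 87.1 to 91.5). A background in both groups could give this as well.

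B cell and immunoglobulin transcripts changed in both comparisons with DAHB. Fewer B cells in the DAHB than in the NaCl libraries would be argued against by the deposited scaling alone, where besides Ighm 4 of the 10 other markers were called higher and 4 lower, and stayed open once the bound was made to cover quantile normalization, where 1 marker was higher and 6 were lower. Fewer B cells in the DAHB+O than in the DAHB libraries may explain the fall with oligomycin, where 8 of 11 markers were lower and none was called higher. Most of the CD8 T cell identity genes were lower in that comparison too, so a fall of markers need not mean a smaller share of B cells. A smaller B cell share as the only source is argued against for Ighm and Igkc, as Igkc changed by -1.88 more than Ighm on the log2 scale (SE 0.125). No biological explanation was tested for this pattern.

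Glycolysis genes fell with oligomycin, 20 of 22. Scaling between libraries is argued against, since after quantile normalization 20 of the 22 were lower and the median of the list was -0.71 on the log2 scale (bounds -0.96 to -0.68), against -0.84 as deposited. The MYC and ribosome biogenesis list rose with a median of 0.59 (bounds 0.46 to 0.69), which argues against lower MYC activity only if that list reads it. The list did not follow Myc RNA in DAHB against NaCl, where 33 of its 42 genes fell and 3 rose while Myc was higher. A candidate explanation is lower HIF-1 activity, as 21 of 22 HIF-1 targets outside the glycolysis list fell with a median of -1.12 (bounds -1.63 to -0.81). It was found and tested on the same data, and HIF-1 itself was not measured. Of the 19 glycolysis genes outside the HIF-1 list 17 fell too. That list need not hold every HIF-1 target, so their fall does not decide the question.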
